A study of Mus musculus with 4 samples.

How the data were processed

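CTCF-bound DNA and input DNA were sequenced from splenic B cells and splenic plasmablasts of mice, with 1 CTCF and 1 input library per cell type (4 samples). Per the labels' protocols, fixation took 10 minutes in formaldehyde at 1% and chromatin was sheared to fragments averaging 200 to 400 bp. An immunoprecipitation used 30 µg of chromatin with a CTCF antibody, and 10 ng of DNA went into each library. Also per the labels' protocols, the B cell libraries were run on an Illumina Genome Analyzer II lane and the plasmablast libraries on a HiSeq lane. Per the submitters' processing notes, Bowtie, HOMER and the mouse build mm9 were used. Their versions, the peak thresholds and the use made of the input are not given in the sources used here.

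The data analysed were the 2 peak lists the authors deposited, 1 per CTCF library, with the chromosome, start, end, name, score and strand of each peak. Nothing in the sources names pooled replicates. The unit of the score in the deposited files is not stated. Its values below 20 fall on a regular grid (tolerance 0.05): all 11 different values in B cells on steps of 0.926 and all 110 in plasmablasts on steps of 0.178. The B cell step was 5.20 times the plasmablast step, and the median score was 67.1 steps in B cells and 109 in plasmablasts. If a step were 1 read scaled to a fixed total, the plasmablast library would be about 5.20 times as deep. The lowest score, however, is 11.0 steps in B cells and 1.12 in plasmablasts, and 1 read is too low for a called peak. What a step stands for was therefore left open, and the depth of the libraries is unknown. Scores were used only to rank and describe peaks within a list, except for the rank correlation over shared sites and for X to autosome ratios, which are relative to the same library. The numbers in the peak names have gaps: 36381 listed B cell peaks against a sum of 57501 for the highest number of each chromosome, and 31086 against 51868 in plasmablasts. Positions were read as BED, so 1 was added to each start. Input libraries were not analysed here.

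A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and the counts were checked with bedtools 2.31.1, which gave 24702 shared peaks in either list. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Deciles were formed on each list's own score. Local density was the number of shared sites within 500 kb, and windows of 1 Mb were used if they held at least 10 unshared peaks. For the X chromosome, each shared site was also compared with the median of autosomal shared sites of the same decile of the other library's score, and intervals came from 1000 bootstrap draws over sites. The window, run, density, rank correlation and X chromosome comparisons were chosen after seeing the data, and the overlap and strength comparisons before the data were examined. Tested on simulated data for the B cell against plasmablast comparison (36381 peaks), the overlap recovered 100% of the peaks left in place and 0.234% of those moved away, and an X ratio simulated at 0.50 came out at 0.55. The peaks left in place were offset by too little to lose their overlap, so the 100% was fixed in advance. Simulated plasmablast scores were the B cell scores with noise, which was not set to the real correlation between the libraries. The recovered ratio was closer to 1 than the simulated one there, which need not hold for the real data.

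The peaks named in the text follow a rule fixed before the data were examined: the 5 highest scoring shared and the 10 highest scoring unshared peaks of each list, of which those that matter are given in full. The rule's gene parts could not be applied. Promoter shares, CTCF motif shares and the 14 gene lists planned needed an mm9 annotation or genome, which was not used here, and the gene table at hand is on GRCm38. No gene is therefore named, and loci are named only by the chromosome known to carry them. Alternatives were another overlap rule, stricter lists, other chromosomes and merged peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures in matplotlib 3.10.9.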

Results

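CTCF is a zinc finger DNA-binding protein known as an insulator and chromatin loop anchor. Its binding was mapped by chromatin immunoprecipitation sequencing in 2 cell types of C57BL/6 mice. The labels give an age of 6 weeks for the mice of both cell types. Splenic B cells were taken as the CD43-negative fraction of spleens. Plasmablasts, the dividing antibody-secreting progeny of activated B cells, were sorted as CD138-positive spleen cells 3 days after an injection of 50 µg lipopolysaccharide. Each cell type had 1 CTCF library and 1 input library, and 1 peak list per CTCF library was analysed. The B cell list held 36381 peaks of 305 bp, and the plasmablast list held 31086 peaks, of which all but 1 were 179 bp wide. The peak scores, which are the authors' own values, had a median of 62.1 (quartiles 27.8 and 142.6) in B cells and 19.4 (quartiles 9.6 and 37.7) in plasmablasts. With 1 library per cell type there was no replicate spread, so no p-value was computed between the cell types. The libraries also differed in sequencing instrument, so an instrument difference and a cell type difference cannot be separated.

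The first comparison asked which CTCF sites were listed in both cell types. Most sites were common to B cells and plasmablasts: 24702 peaks of each list overlapped a peak of the other by at least 1 bp. These were 67.9% of the B cell peaks (exact 95% binomial interval 67.4 to 68.4%) and 79.5% of the plasmablast peaks (79.0 to 79.9%). Above the median score of each list the order turned, with 93.9% of the B cell and 89.8% of the plasmablast peaks shared. The remaining 11679 peaks of the whole lists were listed only in B cells and 6384 only in plasmablasts. The intervals cover counting error only. The midpoints of shared peaks lay a median of 17 bp apart, and 88.2% lay within 50 bp of each other. When the B cell peaks were displaced by 10 to 50 kb in either direction, between 1.23% and 1.52% overlapped a plasmablast peak.

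Sharing depended steeply on peak strength, and the strongest CTCF sites of B cells were almost all listed in plasmablasts. In the highest decile of the B cell list by score, 3657 of 3669 peaks were shared (99.7%, interval 99.4 to 99.8%). In the lowest decile 12.3% were shared (11.2 to 13.4%). The plasmablast list had a shallower gradient, from 55.9% in its lowest decile (54.1 to 57.6%) to 96.8% in its highest (96.1 to 97.4%). Since depth is unknown, a difference in depth between the libraries may contribute to the unlike gradients. The median score of unshared B cell peaks was 24.1, against 104.7 for shared ones. In plasmablasts the corresponding medians were 10.3 and 23.1. Of the unshared peaks, 90.5% of those in B cells and 75.1% of those in plasmablasts lay below the median score of their own list. Over the 24702 shared sites the scores of both libraries had a Spearman rank correlation of 0.70. This correlation is across sites, which are not independent replicates.

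**Figure D1:**
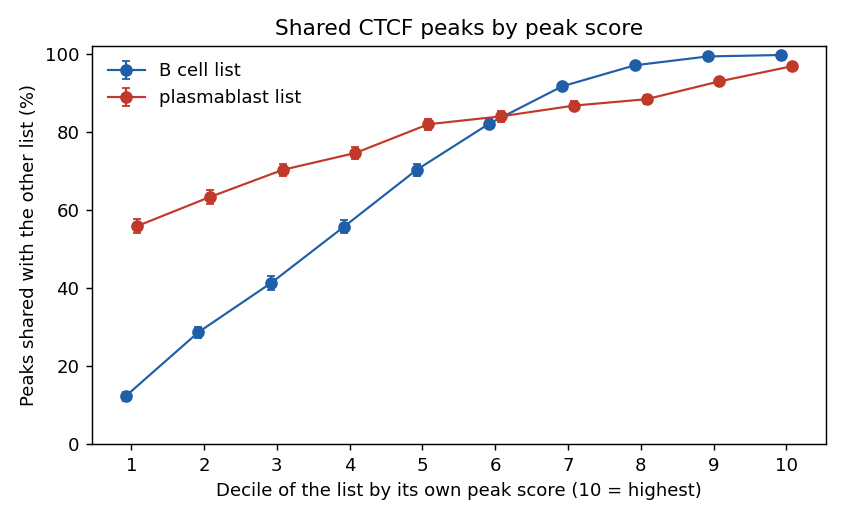
Percentage of CTCF peaks that overlap a peak of the other list (vertical axis), by decile of the list ranked on its own score (horizontal axis, 10 highest), for the B cell list and the plasmablast list. Bars are exact 95% binomial intervals; the share climbs from 12.3% to 99.7% in B cells and from 55.9% to 96.8% in plasmablasts.

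The 5 highest scoring shared sites were not the same in the lists, though most of them ranked high in both. In B cells the top 5 shared peaks (mm9, 1-based) were on chromosome 10 at 79627803 to 79628107 with a score of 439.9, chromosome 7 at 142927348 to 142927652 (433.5), chromosome 2 at 26502418 to 26502722 (426.0), chromosome 12 at 109996211 to 109996515 (424.2) and chromosome 17 at 36133895 to 36134199 (422.3). The plasmablast peaks at these sites lay at the 99.5th, 98.5th, 83.2nd, 98.3rd and 98.7th percentiles of their list, in that order. In plasmablasts the top 3 were the last listed peaks at the distal end of the X chromosome. They began at 166417091 (score 478.9), 166428152 (436.0) and 166425031 (275.0). The corresponding B cell peaks scored 277.9, 364.9 and 278.8 and lay above the 97th percentile of the B cell list. Whether these X sites lie in repeated sequence, which can raise a score, was not checked, since no mm9 sequence was used here. The next-ranked plasmablast peaks were on chromosome 1 at 183819026 to 183819204 (200.6) and chromosome 9 at 111192465 to 111192643 (185.5), and their B cell counterparts scored 403.8 and 396.4.

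Strong sites listed in only 1 cell type were few, and in B cells they mostly adjoined a plasmablast peak. Of the 10 highest scoring B cell peaks with no overlap, 8 had a plasmablast peak with its midpoint within 500 bp, as at chromosome 11 position 11361903 to 11362207 (score 277.9, nearest plasmablast midpoint 349 bp away). The 2 others were at chromosome 17 position 39980139 to 39980443, the top peak of the whole B cell list (533.5), and at chromosome 1 position 159009507 to 159009811 (227.8). The nearest plasmablast midpoints to these lay 1974 and 2255 bp away. Those plasmablast peaks were strong too, with scores of 179.6 and 89.2 at the 99.98th and 99.3rd percentiles of their list. The former was also the highest scoring unshared plasmablast peak, so the chromosome 17 locus ranked near the top of both lists. Repeated sequence was not checked for at this locus either, so its high scores need not mark strong CTCF binding. Of the 10 highest scoring unshared plasmablast peaks, 3 lay within 500 bp of a B cell peak and 5 lay more than 1 kb away. The most isolated of these were at chromosome 1 position 141164523 to 141164701 (score 76.0), 96380 bp from the nearest B cell midpoint, and chromosome 9 position 96473778 to 96473956 (90.3), 24643 bp away. In the highest decile of each list, 12 B cell peaks and 99 plasmablast peaks were unshared. None of these B cell peaks and 20 of these plasmablast peaks lay more than 10 kb from a peak of the other list.

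The run with the most plasmablast peaks was on chromosome 12, the chromosome that carries the immunoglobulin heavy chain locus. Between positions 114454246 and 114462705, a stretch of 8.46 kb, plasmablasts had 8 peaks with scores from 40.8 to 91.0, each within 2 kb of the next. B cells had 3 peaks in that stretch, and 2 of the 8 plasmablast peaks overlapped one. The third B cell peak, at 114460284 to 114460588, had a score of 354.7 and lay at the 99.7th percentile of its list. Its midpoint was 250 bp from that of the plasmablast peak at 114460597 to 114460775 (score 91.0), so the intervals did not touch. No other run with gaps of at most 2 kb held more than 4 peaks in either list. There were 12 runs of at least 4 peaks in plasmablasts and 3 in B cells. Runs of at least 2 peaks went the other way, with 1957 in plasmablasts and 2166 in B cells. Peaks were 305 bp wide in B cells and 179 bp in plasmablasts, with smallest gaps of 244 and 193 bp. The plasmablast list thus held peaks closer together, a difference in resolution that the run counts do not allow for. The position of this run relative to the genes of the locus was not determined, since no mm9 annotation was used here.

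On chromosome 6, which carries the immunoglobulin kappa light chain locus, the plasmablast list held more sites than the B cell list over a 3 Mb stretch. From 67000001 to 70000000 it held 32 peaks against 16 in B cells. Of these sites 12 were shared, 4 were in B cells only and 20 were in plasmablasts only. The 20 plasmablast-only peaks had a median score of 9.15, and 1 of them lay above the median score of the plasmablast list. Chromosome 17 carries the mouse major histocompatibility complex, and its window from 34000001 to 35000000 was among the 6 richest of the genome in shared sites. It held 52 shared, 21 B cell only and 13 plasmablast only peaks. B cell only peaks were thus 61.8% of the unshared peaks there, against 64.7% genome-wide. The chromosome 6 and 17 regions were chosen after their values were seen, and their overlap with the named loci was not determined.

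**Figure D2:**
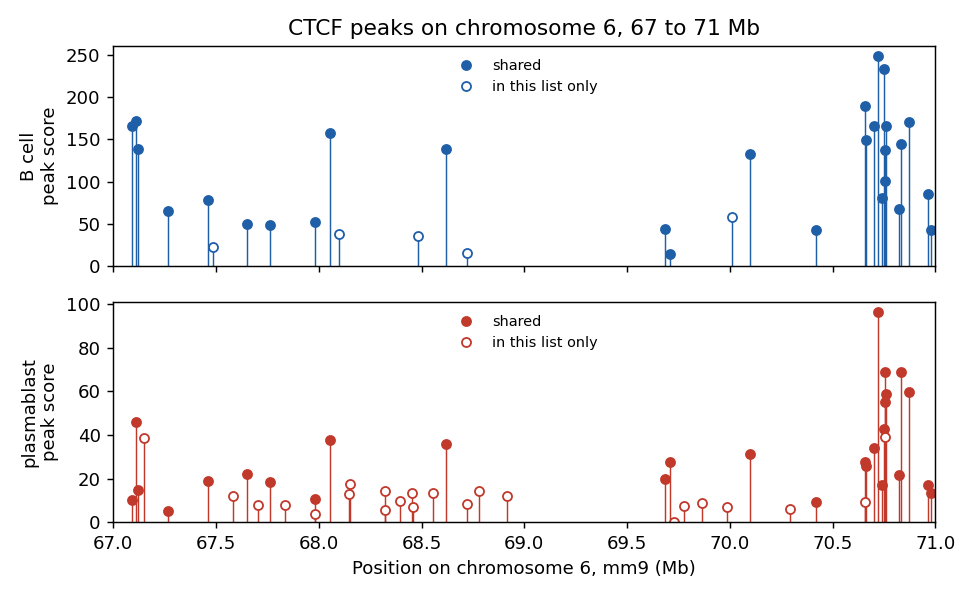
Peak score (vertical axis, each list on its own scale) against position on chromosome 6 in mm9 (horizontal axis, Mb) for B cells and plasmablasts, with filled circles for shared peaks and open circles for peaks in that list only. From 67 to 70 Mb the plasmablast panel has 20 open circles and the B cell panel 4.

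Across 782 windows of 1 Mb with at least 10 unshared peaks, the share of these that were B cell only had a median of 70% and quartiles of 60% and 80%. Its standard deviation over windows was 15.1 percentage points, above the highest of 1000 binomial draws at the genome-wide share (13.7). In 12 windows no unshared peak came from plasmablasts, led by chromosome 5 from 129000001 to 130000000 with 19 B cell only peaks. No window lacked B cell only peaks. Since B cell only peaks were 64.7% of all unshared peaks, windows without plasmablast only peaks were the likelier kind, and no expected number was computed. The windows with the lowest B cell share were on the X chromosome from 50000001 to 51000000 (1 B cell only and 10 plasmablast only peaks), chromosome 3 from 58000001 to 59000000 (2 and 10) and chromosome 6 from 129000001 to 130000000 (3 and 13).

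The X chromosome stood apart from the 19 autosomes. It was the only one of these 20 chromosomes with fewer B cell than plasmablast peaks, 693 against 851, a ratio of 0.81, while the autosomal ratios ran from 1.098 on chromosome 1 to 1.25 on chromosome 19. Of the plasmablast peaks on X, 60.6% were shared (interval 57.3 to 63.9%), below every autosome (74.4 to 83.9%). Autosomal plasmablast peaks of the same score deciles were shared in 76.4% of cases. For B cell peaks on X the shared percentage was 74.5% (71.04 to 77.7%), above every autosome (64.8 to 70.1%). At the 516 shared X sites the median B cell score was 52.8, against 105.6 at the 24186 shared autosomal sites. That is a ratio of 0.50 with a bootstrap 95% interval over sites of 0.46 to 0.56. In plasmablasts the same sites had medians of 18.5 and 23.3, a ratio of 0.79 (0.70 to 0.84). The bootstrap intervals take sites as independent and cover no spread between libraries or animals. Single autosomes ranged from 0.86 to 1.14 in B cells and from 0.92 to 1.07 in plasmablasts. With all listed peaks in place of the shared sites, the X ratios were 0.68 in B cells and 0.71 in plasmablasts, so the libraries lay much closer together on that measure. The B cell list also held 1 peak on chromosome Y and 1 on the mitochondrial genome, and the plasmablast list held none on either.

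**Figure D3:**
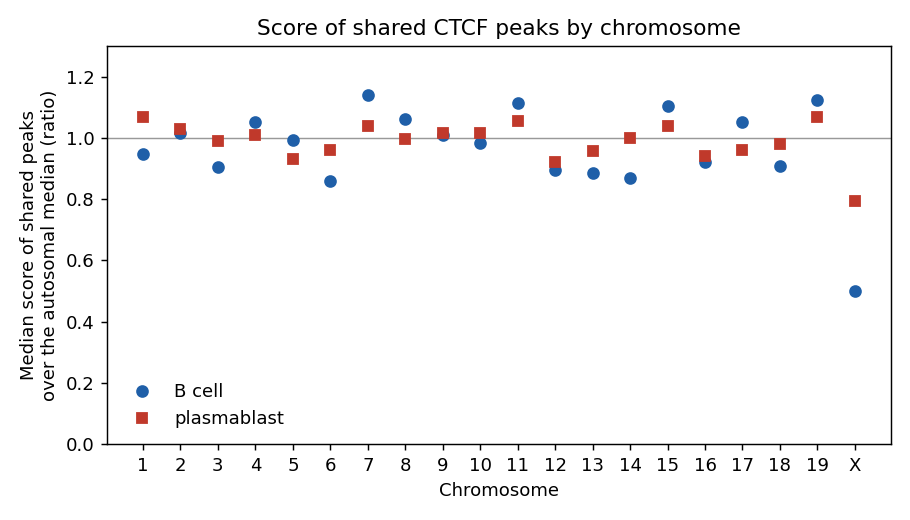
Median score of the shared peaks of each chromosome (horizontal axis) divided by the median over all autosomal shared peaks of the same library (vertical axis, ratio), for B cells (circles) and plasmablasts (squares). The X chromosome lies at 0.50 in B cells and 0.79 in plasmablasts, below all 19 autosomes in both.

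CTCF peak density varied widely between chromosomes in both cell types. Chromosome 11 was the densest, with 24.9 B cell and 20.5 plasmablast peaks per Mb of the span covered by peaks. Chromosome 3 was the sparsest autosome with 10.3 and 9.32 per Mb, and X had 4.26 and 5.23. Unshared peaks were divided into quintiles by the number of shared sites within 500 kb. In the sparsest quintile, with 0 to 7 such sites, 46.2% of the unshared peaks were from B cells (interval 44.6 to 47.9%). In the densest quintile, with 29 to 70 sites, this was 72.7% (71.2 to 74.2%). Shared sites were divided into quintiles of their own by the same measure. At shared autosomal sites the median B cell score went from 75.9 in the sparsest of these (0 to 9 sites) to 137.1 in the densest (32 to 69 sites). The median plasmablast score at the same sites went from 19.8 to 27.1.

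**Figure D4:**
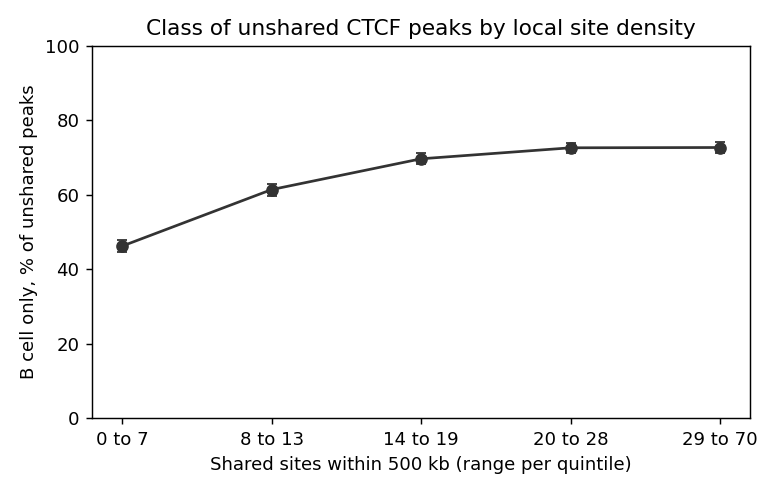
B cell only peaks as a percentage of all unshared peaks (vertical axis) by quintile of the number of shared sites within 500 kb (horizontal axis, range per quintile), with exact 95% binomial intervals. The percentage goes from 46.2% in the sparsest quintile to 72.7% in the densest.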

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

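The shared percentages moved little with the overlap rule. In B cells the 67.9% became 66.1% with 50% reciprocal overlap, 66.6% with midpoints within 100 bp and 68.7% within 500 bp. In plasmablasts the 79.5% became 77.3%, 77.9% and 80.8%. The threshold of the lists mattered more: 93.9% of the B cell peaks above their list's median score and 89.8% of such plasmablast peaks were shared, whereas matching only the 10000 highest scoring peaks of each list gave 69.0% for both. The order of the 2 lists thus differed between the whole lists and the peaks above the median scores. The plasmablast percentage minus that of B cells was 11.6 points over the whole lists. That value follows from the list lengths, since the shared count was the same in both. Above the median scores the difference was -4.13. For the 10000 highest scoring peaks it was 0, which was fixed in advance, since lists of equal length with an equal shared count must give it. This difference was added after seeing the data. With midpoints within 100 bp, the lowest decile fell to 11.1% in B cells and 54.0% in plasmablasts, and the highest decile of B cells to 99.2%. Among other alternatives chosen after seeing the data, the X ratio of B cells was 0.676 over all listed peaks. The gap between the densest and sparsest quintile (26.5 percentage points) was 23.4 on autosomes alone and 39.5 for peaks above the median score of their list, a filter that itself follows density. With the median taken within each density quintile it was 20.5, or 27.2 with quintiles set again among the kept peaks. In all, 15 of 34 alternatives stayed within the counting or bootstrap interval or a set margin, 18 moved and 1, the order of the shared percentages above the median scores, was reversed. Merging peaks within 100 bp changed nothing, since no 2 peaks of a list lie that close. Alternatives on fold over input, promoters, motifs and gene lists were not run, because the lists give no fold and no mm9 annotation was used. With 1 library per cell type, no replicate could be left out. Depth is unknown, so a peak missing from a list is not shown to be absent from the cells.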

Other observations

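Close groups of CTCF peaks in B cells were smaller than the run of 8 plasmablast peaks on chromosome 12. The B cell list had 3 runs of 4 peaks with gaps of at most 2 kb. The run on chromosome 9 from 71460867 to 71465520 was strong, with scores from 108.4 to 205.6, and all 4 of its peaks were shared. The run on chromosome 5 from 31518891 to 31524258 was weak, with scores from 23.2 to 33.3, and 1 of its 4 peaks was shared. On chromosome 1, 4 of the 10 windows of 1 Mb with the lowest B cell share of unshared peaks were found. Those starting at 140000001 and 162000001 each held 3 B cell only and 11 plasmablast only peaks.

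The test of local site density on X was chosen before its result was seen. The other tests here were chosen after, among them the test of weak peaks in the density trend, which replaced an earlier one.

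Unshared peaks lay low in their own list. In the list with fewer such peaks, plasmablasts, 75.1% of the unshared peaks were below the median score. Displaced summits account for a minority: at most 13.2% of the unshared peaks above the median score of a list had a peak of the other list within 500 bp. The other 1380 plasmablast and 1055 B cell unshared peaks above the median score had none that close. A calling threshold stays open as a candidate explanation for the weak unshared peaks: the 75.1% restates the pattern and does not test it, and no replicate library shows how often a weak peak is listed again.

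X-linked sites were weak in the B cell library relative to autosomal sites of like strength in plasmablasts. At matched plasmablast score, the median X site had 0.64 of the autosomal B cell score (bootstrap interval 0.59 to 0.70). In the reverse match, at like B cell score, it had 1.22 times the autosomal plasmablast score (1.13 to 1.29). Both go the same way, which argues against a mere compression of weak sites. The size depends on which score is matched, so 0.64 is not taken as the size of the shift. Matching on plasmablast score and on quintile of local site density gave a B cell ratio of 0.71 (0.66 to 0.77). X was sparser in peaks than every autosome, and the sparsest quintile of autosomal sites spans 0 to 9 sites. Density was not matched within that quintile, so how much of the difference it accounts for stays open. All 9 blocks of 20 Mb with at least 20 sites had a B cell ratio at matched plasmablast score below 1 (0.49 to 0.82). However, X sites were weak in both libraries, and their scores had a rank correlation of 0.49. An imperfect correlation can alone lower this ratio at weak sites. The reverse match was not run by block, so a single stretch behind the shift is not excluded. A difference in the sex of the animals or X dosage of the cell types may lie behind the shift. The options cannot be told apart because the labels give no sex and each cell type has 1 library. The B cell list held 1 peak on chromosome Y and the plasmablast list none, which is too little to decide.

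Unshared peaks were more often from B cells where shared sites were dense. A gap remained among the stronger unshared peaks, so the weakest peaks alone do not account for the whole trend. Scores of shared sites rose in rank with density, more steeply in B cells, so a filter at the median of the whole list builds in part of a trend, and the median was taken within each density quintile instead. Among the unshared peaks above it, the B cell share was 25.1% (95% interval 22.3 to 28.0%) in the sparsest and 45.5% (39.8 to 51.3%) in the densest quintile, a gap of 20.5 percentage points. The rise was not steady, since the fourth quintile had 52.2%. This filter was not repeated on autosomes alone, so the part that X has in the remaining gap is not known. The sequencing instrument and base composition stay open for the whole trend of 26.5 percentage points. They cannot be told apart from cell type, because each cell type was run on its own instrument and no mm9 sequence was used here.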
